A study of Arabidopsis lyrata and Arabidopsis thaliana with 4 samples.

How the data were processed

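Total RNA of 4 samples was size fractionated, adaptors were ligated in series to both ends of the small RNAs, and the products were amplified by RT-PCR and sequenced on an Illumina Genome Analyzer, per the labels' protocols. The authors trimmed the 3' adaptor by computer, per the series' design text, which also says that unprocessed reads of both flower libraries are unavailable. The deposited values are raw counts of reads per distinct sequence, listed by the authors once for every place where the sequence matches the genome. Every listed place spanned exactly the length of its sequence, and in the 4 files no sequence had different counts at different places, as checked on all 9551535, 14426190, 11868877 and 2578047 places. The aligner, the mismatch rule, any filter and the genome builds are not given in the sources used here. Ligation and amplification can favour some sequences over others, so levels of different sequences in 1 library are less comparable than levels of 1 sequence in libraries prepared alike. The labels do not say whether the libraries were prepared together.

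Each distinct sequence was counted once per library, which gave 4036969 reads for leaves, 4876856 and 4229434 for the flower replicates and 3903749 for A. thaliana. Lengths ran from 15 to 30 nt in leaves, 15 to 33 nt in flowers and 18 to 30 nt in A. thaliana. Sequences with 1 place held 56.04%, 42.0%, 42.66% and 73.25% of the reads. The 3 A. lyrata libraries held 3260001 distinct sequences, of which the 33585 with at least 30 reads, holding 47.51% of the reads, were tested. At these depths the 95% interval of a length share of all reads was within 0.05 percentage points of its value, and a count of 0, taken to allow up to 3 counts, allowed 0.743 RPM in leaves, 0.615 and 0.709 in the flower replicates and 0.768 in A. thaliana.

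Samples were grouped by the labels into A. lyrata leaves (1), A. lyrata flowers (2) and A. thaliana aerial tissue (1). Leaves were compared with flowers by the two-sided quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with TMM factors and Benjamini-Hochberg adjustment, and features with adjusted p under 0.05 were called. Ratios and bounds of leaves against flowers used the same TMM factors, and those between species used library totals. The spread came from the 2 flower libraries, with 1 residual degree of freedom moderated across features, and the lone leaf library was assumed to vary like them. The same test was run on summed families and on 1 kb windows of 21 or 24 nt reads, using sequences with 1 place and at least 30 reads per window. A. thaliana was compared with the mean of leaves and flowers over the catalogue, with TMM factors from the catalogue and at least 30 reads. The sequence, window and species tests were tested on simulated counts with 200 changed features, or 15 in the species comparison, and the summed-family test was not. Sequences recovered 39% and 69% of changes by a log2 of 2 and 4, and 24 nt windows 44% and 67%. The 21 nt windows recovered 64% and 81%, and the species comparison 87.5% and 100%. Larger shares of features were called in the data than were changed in the simulations, so these rates need not hold for the data.

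The catalogue held 77 known A. thaliana miRNAs and tasiRNAs, and a read counted only if it matched exactly. It was sorted into 10 lists: conserved, lineage-limited, phase change, leaf and organ shape, auxin, flower development, nutrient, small RNA pathway, tasiRNA pathway and pollen. Members that differ by few bases, such as miR159a and miR159b or miR172a and miR172c, were kept apart by exact matching, but a sequence shared by several precursors cannot be assigned to 1 of them. The median fold of each list was placed among 10000 random lists of 20 to 22 nt sequences matched on abundance. Random lists describe these libraries and are no test across samples.

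The A. thaliana coordinates of the authors' file were compared with TAIR10.1, and 2.27% of its places held the listed sequence there, so the file uses other coordinates. Sequences were matched anew to TAIR10.1 instead, and 741793 of 741824 sequences of at least 19 nt had an exact match. Of the 77 catalogue members, 75 equal a mature miRNA annotated there. A. lyrata positions are those of the authors' files, and an A. lyrata genome was not used here.

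The items named were set by a rule: the 12 catalogue members with the largest fold in each direction among those called, up to 4 members per list with the highest mean RPM, the 3 sequences outside the catalogue and the 3 windows with the largest fold in each direction, the 10 members with the largest fold in each direction between species with those having at least 100 reads in 1 species and 0 in the other, and the 5 most abundant members per library. The design, the catalogue, this rule and 46 alternatives were fixed before the data were examined. The alternatives, joined later by 1 chosen after seeing the data, were other scalings, DESeq2 1.42.0, other read minimums, sums over the first 18 bases, reads divided by places, 500 nt windows, other weightings of the length shares and leaving out each flower replicate. DESeq2 gave no adjusted p for 1912 sequences and 4026 windows of 24 nt. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.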

Results

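Small RNAs were sequenced from Arabidopsis lyrata, strain MN47, and from Arabidopsis thaliana, accession Col-0, in a study whose title concerns the evolution of MIRNA genes in this pair of species. The A. lyrata samples were 1 library of rosette leaves from vegetative plants and 2 libraries of flowers of stages 1 to 12. The A. thaliana sample was 1 library of all aerial tissue of plants that were bolting and flowering at an age of 21 days. The leaf library held 4036969 reads of 889740 distinct sequences. The flower libraries held 4876856 reads of 1636295 sequences (replicate 1) and 4229434 reads of 1369093 sequences (replicate 2), and the A. thaliana library held 3903749 reads of 741843 sequences. The flower libraries differed from each other by more than sampling noise (chi-square per degree of freedom of 8.748 over 5307 sequences), so they were treated as 2 replicates. The labels do not say whether they came from separate plants, so the p-values below measure only the spread between these libraries, which may be technical. The leaf and A. thaliana samples had no replicates. Levels are given in RPM, scaled to all reads of the library, intervals are 95% intervals, and intervals and floors cover counting error only. Folds, ratios and bounds of leaves against flowers use TMM factors, which put leaves 1.75 times higher against flowers than library totals do for sequences and 1.89 times higher for 24 nt windows.

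By reads, the most frequent small RNA length in leaves was 21 nt, the usual length of plant miRNAs, and in flowers it was 24 nt, the length of most siRNAs that direct DNA methylation. Reads of 21 nt made up 46.0% of the leaf library (exact binomial interval 45.968 to 46.065) and 15.2% ± 0.009 of the flower libraries (mean ± SD, n = 2). Reads of 24 nt made up 28.1% in leaves (28.064 to 28.152) and 44.4% ± 2.01 in flowers. The A. thaliana library had 56.0% at 21 nt (55.936 to 56.034) and 24.5% at 24 nt (24.453 to 24.539), by reads closer to the A. lyrata leaves than to the flowers. A U was the first base of 82.7% of the 21 nt reads in leaves, of 53.04% and 53.27% in the flower libraries, and of 90.71% in A. thaliana. Within A. thaliana, 89.4% of the 21 nt reads lay in annotated MIR precursors of the TAIR10.1 genome, and 62.39% of the 24 nt reads lay between annotated genes. With 1 leaf library against 2 flower libraries the smallest exact permutation p is 1/3, so the shares were not tested. Both statements rested on few sequences and turned without the 10 most abundant of each library: 24 nt then led in leaves too (42.9% against 20.7% at 21 nt), and A. thaliana (14.8% at 21 nt, 49.3% at 24 nt) was closer to the flowers (10.2% and 50.3%).

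**Figure D1:**
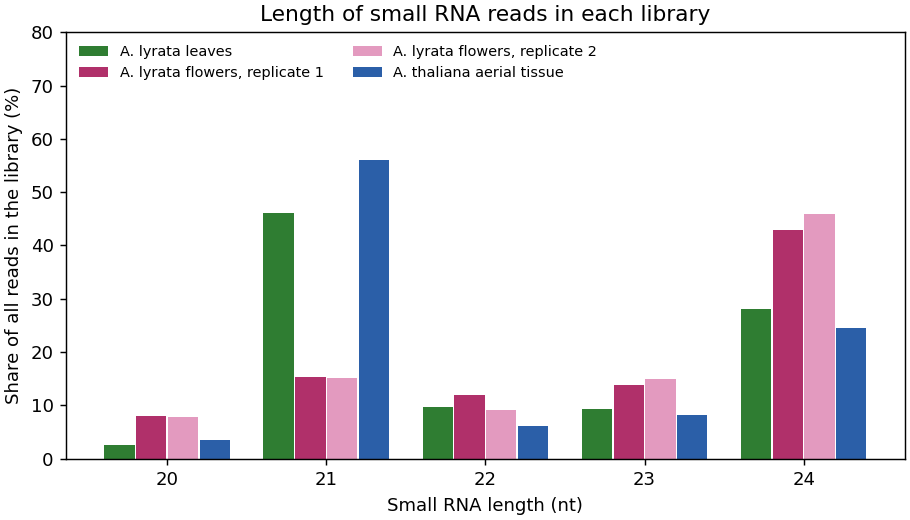
Share of all reads of each library (y axis, percent) by small RNA length (x axis, nt), with 1 bar per library and no error bars. At 21 nt the A. lyrata leaves (46.0%) and the A. thaliana library (56.0%) stand above both flower libraries, which stand highest at 24 nt (mean 44.4%).

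Among known Arabidopsis miRNAs, the largest differences between A. lyrata leaves and flowers were in miR159, higher in leaves, and in miR156 and miR157, higher in flowers. miR159a, which targets GAMYB-like transcription factor genes, stood at 182000 RPM in leaves and 220 ± 1.75 RPM in flowers (log2 fold of leaves over flowers 10.50, SE 0.44, edgeR adjusted p = 1.31e-30). Its relative miR159b stood at 86500 and 39.4 ± 1.48 RPM (log2 11.91, SE 0.45). miR156a, which targets SPL genes and maintains the juvenile phase, stood at 3.22 RPM in leaves and 45600 ± 645 RPM in flowers (log2 -12.97, SE 0.66, edgeR adjusted p = 7.79e-27). The closely related miR157a had 3 reads in leaves against 60370 and 49546 in the flower libraries, which was 9290-fold lower with a counting interval of 3180 to 45000. In the A. thaliana library, whose tissue included flowers, miR159a and miR159b stood at 350000 and 109000 RPM, and miR156a and miR157a at 0.768 and 1.02 RPM.

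Of 77 known miRNAs and trans-acting siRNAs (tasiRNAs) in the catalogue fixed beforehand, 41 had enough reads for the test of leaves against flowers. Of these, 27 were higher in leaves, 12 were lower, and 2 did not pass (miR172e and miR169b). Over 30 summed families, 21 were higher and 9 lower. All catalogue members together made up 30.86% of the leaf reads, 8.81% and 8.5% of the flower reads and 49.25% of the A. thaliana reads. The 5 most abundant members of the leaf library, in order, were miR159a, miR159b, miR168a, miR167a and miR172a, and the same 5 in the same order led the A. thaliana library. In both flower libraries the order was miR156a, miR157a, miR158a, miR168a and miR166a. These shares and ranks count exact A. thaliana sequences alone and can miss A. lyrata forms. A sequence 1 base from miR825 had 56031 leaf reads, more than miR167a with 43277. Another, 1 base from miR157a, had 50993 reads in flower replicate 2, more than miR157a with 49546. For the group counts that follow, counts adjusted over the list alone were equal to those adjusted over all sequences.

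Among miRNAs of phase change, 1 of 5 was higher in leaves, 3 were lower and 1 did not pass. miR172a, which targets AP2-like genes, was higher in leaves (4530 against 541 ± 127 RPM, log2 3.88, SE 0.32) and stood at 2450 RPM in A. thaliana. Its variant miR172c was lower (log2 -4.03, SE 0.55). The sign turned to 3.78 when all sequences sharing its first 18 bases were summed, but that sum also counts the far more abundant miR172a. miR172e did not pass (log2 -0.43, edgeR adjusted p = 0.258) except with library totals, factors from 20 to 22 nt sequences or a minimum of 10 reads (-1.24, -1.36 and -1.15). The median of this list, -4.03, lay at percentile 17.5 of 10000 random lists matched on abundance.

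The auxin list had 4 members higher and 1 lower of 5 tested, or 3 and 1 with factors from 20 to 22 nt sequences, where miR393a did not pass. miR160a and miR167d, both of which target ARF genes, were higher in leaves, with log2 folds of 6.92 (SE 0.36) and 8.27 (SE 0.39), and so was miR167a at 2.70 (SE 0.32). In A. thaliana miR160a, miR167d and miR167a stood at 228, 283 and 7210 RPM. miR390a, which triggers the tasiRNAs that target ARF genes, was lower in leaves (20.3 against 3430 ± 514 RPM, log2 -6.59, SE 0.47) and stood at 214 RPM in A. thaliana. The median of the list was 2.70, at percentile 54.6. In the tasiRNA pathway list both tested members were lower in leaves, miR390a and miR173, with a median of -7.85 at percentile 7.6. miR173, which triggers tasiRNAs from TAS1 and TAS2 transcripts, stood at 1.49 RPM in leaves, 1460 ± 140 RPM in flowers and 1.28 RPM in A. thaliana (log2 -9.11, SE 0.57). miR828, the trigger of TAS4 tasiRNAs, had 21 reads in leaves and 0 in both flower libraries, at least 27.6-fold higher over the floor of 3 counts in the flower libraries together (15.8-fold with library totals), and was below the 30 reads needed for the test.

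The leaf and organ shape list had 4 members higher and 4 lower of 8, but 4 higher and 1 lower with the median-ratio factors or DESeq2, where miR164a, miR164c and miR166a did not pass, and 3 higher and 4 lower with factors from 20 to 22 nt sequences, where miR319a did not pass. miR396b, which targets growth-regulating factor genes, and miR319c, which targets TCP genes, were higher in leaves (log2 4.56, SE 0.33, and 6.49, SE 0.47). miR165a and miR166a, which target HD-ZIP III genes, were lower (log2 -4.11, SE 0.41, and -1.41, SE 0.35), as was miR164a, which targets NAC genes of organ boundaries (log2 -1.17, SE 0.34). In A. thaliana miR396b and miR319c stood at 612 and 252 RPM, and miR165a, miR166a and miR164a at 97.1, 1390 and 130 RPM. The median of this list, 0.15 at percentile 35.7, ran from -0.77 with factors from 20 to 22 nt sequences and -0.66 with library totals to 1.05 with the median-ratio factors. Of the 11 tested miRNAs of flower development, 8 were higher in leaves, 2 were lower and 1 did not pass (median 3.88, percentile 63.5; 7 and 3 with factors from 20 to 22 nt sequences), miR159a, miR159b and miR167d among the higher ones and miR164c (log2 -1.46, SE 0.42; not past the threshold with the median-ratio factors or DESeq2) and miR172c the lower ones. miR159c had 194 reads in leaves and 0 in both flower libraries, at least 255-fold higher (146-fold with library totals).

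Of the nutrient list, 3 of 13 members were tested and all 3 were higher in leaves (median 3.29, percentile 73.8), but only 2 with library totals or with factors from 20 to 22 nt sequences, where miR408 did not pass. miR398b, which targets copper/zinc superoxide dismutase genes, had 131 reads in leaves and 0 in both flower libraries, at least 172-fold higher (98.5-fold with library totals). miR399b, which targets the phosphate regulator PHO2, and miR408, which targets genes of copper proteins, had log2 folds of 3.29 (SE 0.51) and 1.55 (SE 0.38). In A. thaliana miR398b, miR399b and miR408 stood at 208, 3.33 and 1320 RPM. miR395b, of the sulfate response, had 21 leaf reads and 1 flower read, a scaled ratio of 82.8 (13.3 to 3430), and was not tested. miR827, also on this list, had 0 exact reads in A. lyrata. A sequence 1 base from it (U21G) went the other way, with 8 reads in leaves and 374 and 649 in flowers (log2 -5.03, SE 0.54). The shared direction of the tested members therefore holds for exact matches alone. Of the regulators of the small RNA pathway itself, 1 was higher in leaves and 2 were lower (median -1.25, percentile 36.6). miR168a, which targets AGO1, was higher (15100 against 5630 ± 667 RPM, log2 2.23, SE 0.32), and miR162a (log2 -1.25, SE 0.34), which targets DCL1, and miR403 (log2 -1.52, SE 0.45), which targets AGO2, were lower, though neither passed with the median-ratio factors or DESeq2. The 3 stood at 11300, 50.7 and 3.84 RPM in A. thaliana. Near miR403, the most-read sequence within 300 nt on the same strand went the other way, with 1243 reads in leaves and 4 and 4 in flowers. Those near miR168a and miR162a kept the direction of their miRNA. None of the 3 pollen members reached the test.

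More tested members were higher than lower in leaves, both among deeply conserved miRNAs and among those limited to Arabidopsis and its relatives, and the difference between these lists was not tested. Of 32 conserved members, 20 were higher in leaves, 10 were lower and 2 did not pass (median 2.21, percentile 61.8; 5 lower with the median-ratio factors or DESeq2, and 16 higher and 11 lower with factors from 20 to 22 nt sequences), and of 9 lineage-limited members, 7 were higher and 2 lower (median 2.50, percentile 57.6; 6 and 2 with the last factors). Conserved miR169a, which targets NF-YA genes, had 284 reads in leaves and 2 in flowers, a scaled ratio of 560 (154 to 4650). Both flower reads were in replicate 1, and the log2 was 10.05 without that replicate and 7.89 without the other. Among the lineage-limited members, miR161.1 (log2 8.36, SE 0.38), miR846 (9.14, SE 0.45) and miR824 (5.29, SE 0.33), which targets the MADS-box gene AGL16, were higher in leaves, and these 3 stood at 1240, 1080 and 775 RPM in A. thaliana. miR158a was lower (2.97 RPM in leaves, 8110 ± 2130 in flowers and 7.94 in A. thaliana; log2 -10.60, SE 0.60). In the A. lyrata coordinates of the authors' files, miR159a lay on scaffold 2 at 15958642 to 15958662, miR159b on scaffold 1 at 7594260 to 7594280 and miR158a on scaffold 3 at 4310370 to 4310389, while miR156a had 6 places and could not be assigned to 1 gene. With DESeq2's median-ratio factors the counts were 28 higher and 7 lower, with miR169b newly higher (log2 0.97), and with the DESeq2 test 27 and 7. In both, miR162a, miR164a, miR164c, miR166a and miR403 were no longer past the threshold. All of these but miR166a were also lost at a minimum of 100 reads. Library totals moved the median of the 41 folds by -0.80, the median-ratio factors by 0.90 and factors from 20 to 22 nt sequences by -0.91. With library totals 25 were higher and 13 lower, with miR408 and miR394a no longer past the threshold and miR172e newly lower. With the factors from 20 to 22 nt sequences 22 were higher and 13 lower, with miR319a, miR391 and miR393a lost as well. Summed over the first 18 bases, miR167d, miR169a and miR319c merge with miR167a, miR169b and miR319a, and miR159b merges with miR159a and miR159c. The joint log2 folds, at 2.84, 3.48, 2.15 and 10.77, are therefore not those of single members. The fold of miR846 was smaller in such a sum, at 7.99.

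**Figure D2:**
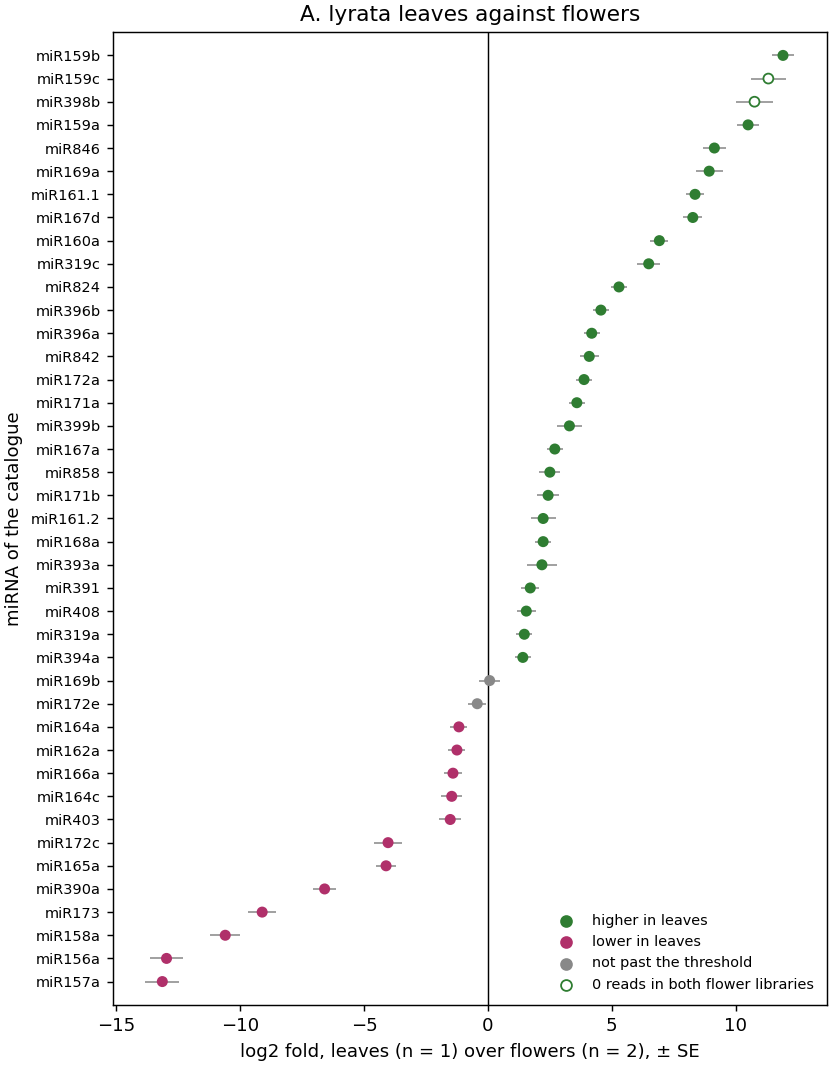
Fitted log2 fold of leaves (1 library) over flowers (2 libraries) on the x axis for each of the 41 tested miRNAs on the y axis, with bars of ± 1 SE. The folds run from -13.14 (miR157a) to 11.91 (miR159b), and the open points, miR159c and miR398b, had 0 reads in both flower libraries and are fitted values, not bounds.

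Among the small RNA sequences tested, 24 nt sequences were mostly lower in leaves, and 21 nt sequences went both ways. The minimum of 30 reads over 1 leaf and 2 flower libraries admits sequences of flowers more easily; within single libraries, 2568 sequences of 24 nt reached 30 reads in leaves and 6036 and 5530 in flowers. Of 17444 tested sequences of 24 nt, 3018 were higher in leaves and 13106 lower, and of 4208 of 21 nt, 2127 were higher and 1629 lower. Over all lengths, 7900 of 33585 were higher and 22651 lower, or 14295 lower with DESeq2. Outside the catalogue, the largest folds toward leaves were in UUGUUGAUCGGAUGGUAGAAA, with 3067 reads in leaves and 0 in flowers (at least 4030-fold), UUGGCCUAUUGAACCUCUGUUU (2241 and 0, at least 2950-fold) and UUGAAUUUUGGUUGAAAGUGA (1921 and 0, at least 2530-fold). They lay on scaffold 4 at 19241142 to 19241162, on scaffold 2 at 17541883 to 17541904 and, for 1 of its 2 places, on scaffold 8 at 22065489 to 22065509. The first has an exact match in TAIR10.1 in the tasiRNA gene TAS2, on chromosome 2 at 16539812 to 16539832. The largest folds toward flowers were in CUGACAGAAGAUAGAGAGCAC (0 reads in leaves, 49809 and 50993 in flowers, at least 8520-fold), which carries the change U1C from miR157a counted from the 5' end, and UUGACAGAAGAAAGAGAGCAC (0, 23701 and 21553, at least 3820-fold), which carries U12A. Their exact matches in TAIR10.1 lie in MIR157d, on chromosome 1 at 18026989 to 18027009, and in MIR156h, on chromosome 5 at 22597087 to 22597107. UACCUGGUUGAUCCUGCCAGUAG, which matches ribosomal RNA, had 0 leaf reads and 7009 and 11040 flower reads (at least 1530-fold). In simulated data of the same size, 39% of sequences changed by a log2 of 2 were recovered and 69% of those changed by 4. Only 200 sequences were changed there, while most were called in the data, so these rates need not hold for the data.

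Across the A. lyrata genome, 1 kb windows of 24 nt siRNAs differed between leaves and flowers in both directions, and the balance of directions depended on the scaling. Of 17302 windows, 4010 had more 24 nt reads in leaves and 5052 fewer (edgeR with TMM, median log2 -0.24), and with library totals the counts were 2108 and 8440. DESeq2 called 1533 and 2001, and with reads divided by places the balance turned, to 10065 higher and 9610 lower of 44846. The windows with the largest folds were on scaffold 2 at 17801001 to 17802000 (158 leaf reads, 0 in flowers, at least 225-fold higher in leaves), scaffold 3 at 8574001 to 8575000 (119 and 0, at least 169-fold) and scaffold 3 at 8569001 to 8570000 (101 and 0, at least 144-fold). Toward flowers they were on scaffold 5 at 13716001 to 13717000 (0 leaf reads, 1944 and 1838 flower reads, at least 295-fold), scaffold 2 at 7673001 to 7674000 (0, 1163 and 961) and scaffold 8 at 3333001 to 3334000 (0, 1048 and 941, at least 155-fold). Windows of 21 nt reads were more often lower in leaves, with 293 higher and 649 lower of 1091, or 661 and 1056 of 2099 with reads divided by places. The largest were scaffold 7 at 884001 to 885000 (1063 leaf reads, 0 in flowers, at least 753-fold), scaffold 2 at 17801001 to 17802000 (2563 leaf reads, 1 flower read) and scaffold 3 at 3257001 to 3258000 (438 and 0, at least 310-fold). Toward flowers they were the windows of the MIR157d and MIR156h sequences above, on scaffold 1 from 24813001 and scaffold 8 from 17184001, and scaffold 7 at 10086001 to 10087000 (0, 1963 and 1364, at least 522-fold). The annotation of these windows was not analysed here, since no A. lyrata genome was used.

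Between the species, a group of young miRNAs, led by miR163, had exact reads in A. thaliana alone, although some of them had close relatives in A. lyrata, and miR156a, miR157a, miR158a and miR173 were lower in A. thaliana than in the mean of A. lyrata leaves and flowers, where flowers held nearly all of their reads. miR163, which targets methyltransferase genes and whose mature sequence lies in MIR163 on chromosome 1 of TAIR10.1 at 24884359 to 24884382, had 7435 reads in A. thaliana and 0 in the 3 A. lyrata libraries, at least 8340-fold over the floor of 3 counts in these libraries together. This bound and those that follow use library totals, and with the TMM factors of this comparison they are 1.59 times smaller. Reads sharing the first 18 bases of miR163 numbered 7602 in A. thaliana and 7, 0 and 2 in the A. lyrata libraries, which brought its log2 to 11.18. miR775 (362 reads, at least 406-fold), miR822 (286, at least 321-fold), miR825 (266, at least 299-fold), miR843 (140, at least 157-fold) and miR845a (105, at least 118-fold) also had 0 exact reads in A. lyrata, but miR825 and miR845a had abundant A. lyrata relatives 1 base away. Exact reads were also 0 for the tasiRNAs siR255 (92 reads, at least 103-fold) and tasiR-ARF (45, at least 50.5-fold), miR447a (82, at least 92.0-fold) and miR823 (68, at least 76.3-fold). Summed over the first 18 bases, siR255 and tasiR-ARF had A. lyrata reads, and their log2 of A. thaliana over A. lyrata was only 0.75 and 1.24. No catalogue member had 100 or more A. lyrata reads and 0 in A. thaliana. This could hardly come out otherwise, since the catalogue holds only known A. thaliana sequences. It cannot show miRNAs found in A. lyrata alone.

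Of 60 catalogue members tested between the species, 34 were higher in A. thaliana, 18 were lower and 8 did not pass (edgeR, A. thaliana against the mean of leaves and flowers). Exact matching to A. thaliana sequences can miss A. lyrata forms, which can raise the number of members higher in A. thaliana. miR156a had 3 reads in A. thaliana and the lowest fold against the mean (log2 -9.51, SE 0.24). Its flower level was 59200-fold higher by library totals (20300 to 287000). With the TMM factors that fold was larger (log2 of A. thaliana over flowers alone -17.41). miR157a (log2 -7.14, SE 0.51), miR173 (-5.78, SE 0.57) and miR158a (-4.91, SE 0.46) followed. Lower in A. thaliana by smaller folds were miR164c (-4.46), miR162a (-2.68), miR403 (-2.14), miR842 (-1.87) and miR171b (-1.74), and miR393a, with 2 reads, stood at a ratio of 0.0985 to leaves (0.0112 to 0.403). These smaller folds were less firm. miR842, miR171b and miR393a did not pass with DESeq2, and miR393a did not pass with library totals. Over the first 18 bases miR171b and miR393a did not pass, and miR164c, there summed with miR164a, was -1.43. Against leaves alone 33 were higher and 7 lower, and miR156a (log2 -1.61), miR162a (-0.63) and miR393a (-2.85) did not pass. In that contrast the signs of 12 called members turned. Of those lower in A. thaliana against the mean, miR390a (3.80), miR165a (2.40), miR158a (1.80) and miR166a (0.95) passed as higher, and miR157a (0.82), miR164a (0.34), miR173 (0.18), miR172e (0.12) and miR403 (0.03) did not pass. Of those higher, miR160a (-1.40), miR167d (-1.20) and miR161.1 (-1.18) passed as lower. Across 60 members, the Pearson correlation of log2 RPM was 0.69 between A. thaliana and A. lyrata leaves, 0.17 between A. thaliana and each flower library, 0.55 and 0.53 between leaves and the flower libraries, and 1.0 within the flower pair; these correlations are across miRNAs, which are not independent replicates. Species, tissue and age cannot be separated with 1 A. thaliana library, and a count of 0 in the leaf library allows up to 0.743 RPM.

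**Figure D3:**
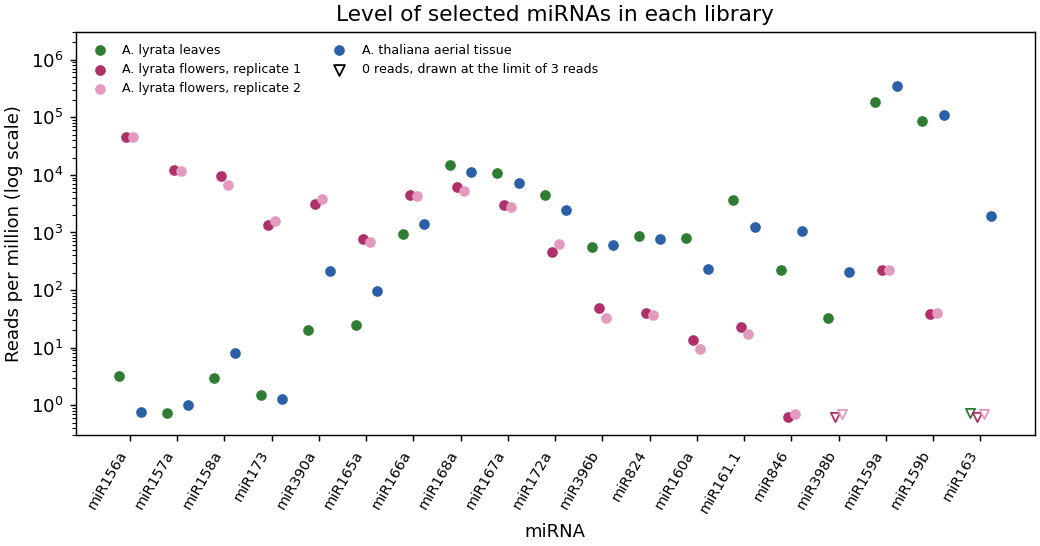
Level of 19 miRNAs (x axis) in each of the 4 libraries, in RPM on a log scale (y axis), 1 point per library and open triangles for 0 reads at the limit of 3 reads. For miR156a, miR157a, miR158a and miR173 the leaf and A. thaliana points lie far below both flower points, and for miR159a and miR159b far above them; miR163 has reads in A. thaliana alone.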

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

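No test in this part was chosen after the result was seen, since it gives counts alone. Reads longer than 30 nt, which the comparisons of length classes did not use, drew attention as a signal outside the main measurement. They made up 0.328% of flower replicate 1 (16018 reads) and 0.373% of flower replicate 2 (15787 reads), and 0 reads in the leaf and A. thaliana libraries. The longest reads were of 30 nt in the leaf and A. thaliana libraries and of 33 nt in both flower libraries. A limit on length in the processing would give the same 0, so no absence can be read from it.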

How the results depend on the processing

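Planned before the data were examined were all alternatives but 1, the length shares over reads of 19 to 30 nt, which was chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Leaving out a flower replicate leaves 1 library against 1 and no test, so counts past 2-fold were compared: 8000 to 8105 sequences higher in leaves and 23165 to 23282 lower, 27 and 12 catalogue members, 21 and 9 families, 4544 to 4554 and 6093 to 6100 windows of 24 nt, 268 to 270 and 642 to 648 windows of 21 nt, and 32 to 33 and 17 to 18 members between species. The flower share of 21 nt was 15.2% without either replicate, and that of 24 nt was 43.0% to 45.8%. Read minimums changed both the number tested and the scaling, and so the counts. The log2 of miR159a, for example, was 9.78 at 10 reads and 11.1 at 100, against 10.5 in the main setting. Its adjusted p changed by many orders of magnitude between these settings, so the size of a p-value should not be read as precision. Sequences higher and lower were 28624 and 85144 at 10 reads and 1776 and 4745 at 100. Of the 24 nt windows, 7737 were lower at 10 reads, and at 100 reads 1381 were higher and 1813 lower. The 21 nt windows were 706 and 1580 at 10 reads and 138 and 176 at 100. Dividing reads by places tested more windows, with 10065 and 9610 of 24 nt and 661 and 1056 of 21 nt. With library totals the 24 nt windows were 2108 and 8440. DESeq2 called 14295 sequences lower, 1533 and 2001 windows of 24 nt and 7 catalogue members lower. Its median-ratio factors in edgeR also called 7 lower. Both lost miR162a, miR164a, miR164c, miR166a and miR403 at equal log2 folds (-0.36, -0.27, -0.57, -0.52 and -0.62), so for these members the scaling made the difference. For sequences and windows the cause was not tested. Against leaves alone, 7 members were lower in A. thaliana, miR157a turned to 0.82, miR158a to 1.80, miR173 to 0.18 and miR403 to 0.03, as this contrast leaves out the flowers, and miR156a (-1.61), miR162a and miR393a no longer passed. Over the first 18 bases siR255 was 0.75, tasiR-ARF 1.24 and miR163 11.18, as A. lyrata reads then count. miR172c turned to 3.78 with the first 18 bases, a sum that also counts miR172a. miR172e, not called in the main setting, turned to 0.46 with the median-ratio factors, 0.46 with DESeq2 and 0.17 at 100 reads. The median-ratio factors and DESeq2 moved the median of the 41 folds by 0.90 and 0.91, about as far as miR172e. Its sign there follows the scaling, which the minimum of 100 reads also changed. Of the values of named members under the alternatives with a test, 216 kept direction and side of the threshold for leaves against flowers, 16 over 6 members no longer passed, 3 newly passed and 4 were the reversed ones above; between species 107 kept both, 9 no longer passed and 4 reversed. Without each flower replicate, which leaves no test, 54 values for leaves against flowers stayed within their spread and 6 moved past it; between species 20 stayed and 20 moved. Length shares depended on weighting. Over distinct sequences, 21 nt made up 11.9% in leaves, 8.1% in flowers and 10.1% in A. thaliana, and 24 nt 49.5%, 50.1% and 50.6%. Over sequences with 1 place they were 64.8%, 18.5% and 68.2%, and 20.2%, 48.6% and 20.8%. Without the 10 most abundant sequences they were 20.7%, 10.2% and 14.8%, and 42.9%, 50.3% and 49.3%. Over 19 to 30 nt, 21 nt made up 47.0% in leaves and 15.8% in flowers, and 24 nt 28.7% in leaves. For leaves against flowers, 36 of 77 members had under 30 reads and were not tested. Depth limits those with few reads, but only 51 of 77 had any A. lyrata read. Exact matching also missed relatives 1 base away, such as those of miR825 and miR845a.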

Other observations

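Chosen after the result was seen were the tests of base differences between the species, of the miR159 share, of the A. thaliana level, of 24 nt sequences picked in flower replicate 1, with TMM and with library totals, and the later forms of the partner-strand test, and the loci described first were picked after their values were seen. A. lyrata had abundant close relatives of several miRNAs whose A. thaliana sequence had 0 reads there. A sequence with the change A6G from miR825 (positions from the 5' end) had 56031 reads in leaves and 11969 and 11733 in flowers (log2 of leaves over flowers 3.22, SE 0.32) and lay on scaffold 4 at 6095752 to 6095772. A sequence with A15G from miR845a, on scaffold 7 at 8114990 to 8115010, had 0 reads in leaves and 5128 and 4251 in flowers. A sequence with U21G from miR827, which acts in the phosphate response, had 8 reads in leaves and 374 and 649 in flowers (log2 -5.03, SE 0.54). None of these 3 had a read in A. thaliana.

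A region of scaffold 4 gave 21 nt siRNAs in large number in all A. lyrata libraries. The window at 19241001 to 19242000, which holds the leaf sequence matching TAS2, stood at 9462 RPM in leaves and 890.9 ± 38.9 RPM in flowers (log2 3.32, SE 0.23), and the window at 19236001 to 19237000, which holds a sequence within 2 bases of siR255, at 8451 and 2927 ± 6.79 RPM (log2 1.44, SE 0.23). miR173, the known trigger of TAS1 and TAS2 tasiRNAs, went the other way, with 6 reads in leaves against 6650 and 6602 in flowers. In A. thaliana, TAS genes of all families together, not TAS1 and TAS2 alone, held 35613 reads (divided by places), while miR173 had 5 reads.

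miR156a, miR157a, miR158a, miR173 and miR390a were far lower in leaves and miR159a and miR159b far higher. The share of reads taken by miR159 is too small to account for this. Leaving miR159a and miR159b out of the library totals could move these folds only slightly, and the median log2 of the 5 went from -11.37 to -10.92. A linear effect of GC content was also too small, since the gap between both sets was 21.11 after a linear correction and 21.61 before. Other effects of GC content were not tested. A candidate explanation is a difference in how the flower libraries captured single sequences, under which the other strand of a precursor would not follow its miRNA. The partner was taken as the most-read sequence within 300 nt on the same genomic strand. Pairing with the miRNA was not required for this choice, so a partner need not be the other strand. Over 11 precursors with 1 place the correlation of both folds was 0.4 (bootstrap interval -0.39 to 0.87, permutation p = 0.22), or 0.35 without the 2 farthest. The Spearman correlation was 0.21 (permutation p = 0.541). These values decide nothing. Widened afterwards to 33 catalogue members, the correlation was 0.2 (-0.12 to 0.5, permutation p = 0.262), and 0.2 without the 2 farthest. Here, and in the count that follows, a miRNA was counted over all its places but its partner was 1 sequence. For miRNAs with several places, both may therefore come from different precursors. The Spearman correlation was then 0.22 (permutation p = 0.219). The folds of miRNA and partner did not share a sign in 14 of the 33, and their median absolute difference was 4.47 log2 units. In a count devised after these folds were seen, 5 of the 7 had a partner more than 3 log2 units from the miRNA beyond counting error. One was miR173, whose partner stood at 3.66 (3.40 to 3.92). By their sequences, the partners of miR156a, miR158a, miR173 and miR390a are largely complementary to these miRNAs. The 5 also include miR159a, whose partner is not complementary to it and so is not its other strand. The limit of 3 was also set then, and the count is not independent evidence. A difference between the tissues stays open and cannot be told apart from library preparation: the sum of miR156a, miR157a, miR158a and miR173 in A. thaliana aerial tissue was only 1.31 times that in A. lyrata leaves (0.81 to 2.11), under the 10 times that a share of flowers was taken to give, but that library is of another species with an unstated share of flowers.

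Single 24 nt sequences differed strongly within windows whose 24 nt total hardly did. Of 355 sequences picked by at least 20 reads in flower replicate 1, 71.55% were over 8-fold lower in leaves and 1.69% in flower replicate 2 (median log2 -4.35 and -0.04), and a first form of this test, on 596 sequences picked by their sum, gave 66.8% past 8-fold against 0.34% within the flower pair; with library totals throughout, picking in replicate 1 gave 69.62% in leaves and 1.27% in replicate 2, of 158. Sampling of low counts does not account for this, as Poisson draws at the pooled level put 0.09% past 8-fold. A capture of single sequences that differs between the flower libraries and the leaf library would give such values, but so would siRNAs cut at other positions of the same loci in each tissue, which was not tested. Picking by flower reads also favours sequences made in flowers.

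Of the 6 catalogue members with at least 100 reads in A. thaliana and 0 in A. lyrata, 2 (miR825 and miR845a) had an A. lyrata sequence within 2 substitutions, and 0 had one when the sequence was reversed. For these 2, exact matching missed an abundant A. lyrata relative. For miR163, miR775, miR822 and miR843 no near sequence of 30 or more reads was found, which leaves open whether the miRNA is lacking, differs further or was not made in the tissues sampled.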
